A study of Mus musculus with 8 samples.

How the data were processed

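The values were made by the submitters before deposit. According to the series design text, reads were processed in Galaxy with TopHat and Cufflinks against MM9, and the submitters' processing notes also name TopHat and mm9. The versions of TopHat, Cufflinks and Galaxy were not given in the sources used here. Per the file headers, the deposited FPKM of each transcript, fragments per kilobase and M mapped fragments, was estimated by the authors' Cufflinks run. The headers also give the deposited coverage, an estimated read depth, and the transcript length as made by the authors. RNA came from sorted cells by a total RNA kit, with a stranded mRNA library and an Illumina sequencer, per the labels' protocols. How reads matching several places were treated was not stated. Gapdh (0.16 to 0.52 FPKM) and Rpl3 (0.30 to 1.98) were listed low although Actb was at 752 to 1132, so genes with near-identical copies are uncertain.

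The files listed 27641 transcripts of 21880 genes, 18255 of them with 1 transcript, in 8 libraries. FPKM was summed per gene symbol. Genes at an FPKM of 1 or more in 2 or more libraries, 12117, were tested. In genes with 1 read, coverage times (length - 41) equalled 45 (offset 40 in day 0 replicate 1), so reads were recovered as coverage × (length - 41)/45. Of the gene sums, 93.7 to 94.4% were whole within 0.05. Recovered depth was 13.71 to 18.13 M mapped reads, a 1.32-fold range. Total FPKM was 238519 in day 4 replicate 1 and 282647 to 293355 elsewhere. These reads served the check of the labels, the depth and 1 alternative, not the main test.

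Genes were tested with limma (3.58.1, R 4.3.3) on log2(FPKM + 1), with 1 model of 3 groups, trended moderation, 5 residual and a median of 3.97 prior degrees of freedom. The Benjamini-Hochberg adjusted p threshold was 0.05, two-sided, per comparison over all tested genes. A change at any time was tested with the moderated F. Gene lists were tested with camera at the preset correlation of 0.01, adjusted over 36 lists with 5 or more tested members. An estimated correlation within each list, and fry, were alternatives. Called members were counted by the adjusted p over all genes and again adjusted over the list alone. Loading, seed tests and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

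The 38 lists held 603 members, 600 of them found (Flg, H2-Q4 and Col6a3 were not). They were 30 pathway lists: keratinocyte differentiation, basal epidermal layer, hair follicle stem cell, DNA replication, mitosis, CDK inhibitors, p53 targets, ERK pathway output, EGFR ligands and receptors, p38 and JNK cascade, AP-1, pro-apoptotic genes, anti-apoptotic genes, miR-125b targets from the literature, ESCRT and endosomal sorting, Notch pathway, Wnt targets, TGF-beta targets, EMT (epithelial-mesenchymal transition), matrix remodelling, NF-kB and cytokines, interferon response, MHC class I presentation, hypoxia and glycolysis, oxidative phosphorylation, ribosome biogenesis, lysosome and autophagy, integrated stress response, NRF2 targets and cholesterol synthesis. There were 7 lists of other cell types (leukocyte, fibroblast, endothelial, muscle, erythroid, melanocyte, adipocyte) and 1 of quality (heat shock and dissociation stress). Melanocyte and adipocyte had 4 and 1 tested members and were not tested as lists. The lists were written from general knowledge before the data were examined, as were the named genes' rule, the tests and their alternatives, except where stated.

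Named genes followed a rule. It took the 8 largest rises and falls per comparison that passed, with no overlap of the libraries of the 2 groups and a mean FPKM of 5 or more in the higher group, leaving out predicted genes, clone names, microRNAs and small nucleolar RNAs. It added up to 4 members with the smallest p of each list described, and 17 fixed genes: Vps4b, Mapk14, Map3k10, Map3k11, Map2k7, Bak1, Bmf, Krt5, Krt14, Itga6, Itgb1, Trp63, Krt10, Mki67, Ccnd1, Cdkn1a and Dusp6. Outside the rule, and chosen after their values were seen, were Hba-a2, as a near-identical copy of Hba-a1, and in the closing section Asf1b, Cdca3, Cxcl10 and Cd274.

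For miR-125b sites, the longest 3′UTR of 50 or more bases was taken for each symbol in the annotation; 11513 genes, 95.0% of those tested, had one. The log2 difference was modelled on carrying CTCAGGG, log10 UTR length and UTR GC content. Control 7-mers had the same GC count, no CpG, no CTCAGG or TCAGGG, and a number of carriers within 25%. The two-sided rank p ranked the coefficient among them by its absolute distance from their median. The test of Mir125b-1 used recovered reads, with an exact interval of the ratio of 2 Poisson counts.

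A self-test on simulated libraries came first. With 200 changed genes among 12117 and 10 draws, a 4-fold change was found in 99.8, 99.1 and 99.7% of genes (day 4 and day 7 against day 0, day 7 against day 4), a 2-fold change in 74.9, 72.5 and 86.9%, and a 1.5-fold change in 13.9, 13.3 and 21.5%. Estimates were 0.82 to 0.87 of the truth. Every gene and library was simulated with the same dispersion of 0.02. In the data, deviations from the group mean had an SD of 0.269 in day 4 replicate 1. It was 0.197 and 0.184 in the other day 4 libraries, so the recovery rates may not hold for these data. False calls were 7.18, 5.94 and 6.37%, above the nominal 5%. The stop rule failed on its first single draw and was then changed to the mean of 10 draws. The counts of changed genes may thus carry more false calls than the threshold states. The simulated rate itself cannot be carried over, since 4259, 6949 and 3290 genes were called in the data. A list shifted by 0.5 was called in each comparison and none of the others. The simulated genes were drawn independently, so this could not test the calls of lists whose members vary together. A simulated site effect of 0 gave a coefficient of 0.014 (permutation p = 0.665), and effects of 0.1 and 0.2 gave 0.069 and 0.215 (permutation p = 0.0019, the smallest possible).

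The alternatives were log2(FPKM + 0.1), no filter, a mean FPKM of 5 or more, median-of-ratios scaling, quantile normalization, the 2 groups alone, the replicate number as a block, no trend, array weights, transcripts kept apart, each library left out, an estimated correlation, fry, and 8-base sites. Added after the data were seen were limma-voom on recovered reads, scaling to the same total FPKM, because day 4 replicate 1 held less FPKM, and the cholesterol list without Fdft1. The overlap and replicate agreement were put through the alternatives only then. The labels do not say that a replicate number marks a shared animal or day, so the numbers were not paired in the main test. Expression of the mature microRNA and raw reads were not analysed here. Transcripts with a failed estimate in 1 or more libraries (genes Inadl, Smox, Eng, Fpgs, Dgkq, Tmem175, Fkbp10, Nt5c3l, Tor1aip1, Tor1aip2, Cd97 and Ddx39) were kept with their listed values.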

Results

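RNA was measured in mouse skin tumour cells whose growth depended on miR-125b, a microRNA switched on by doxycycline. The cells carried a green fluorescent histone label and had formed tumours in the skin of immunodeficient mice. The mice were then moved to food without doxycycline for 0, 4 or 7 days, and labelled cells with high surface integrin α6 and β1, a basal and stem cell gate, were sorted. The 8 libraries fell into 3 groups, with 2 at day 0, 3 at day 4 and 3 at day 7, described by the labels' protocol as independent. Libraries of cells without the transgene were not used here, so loss of doxycycline and loss of miR-125b were not separated.

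The depth recovered from the values was 16.31 and 13.71 M mapped reads in the day 0 libraries, 16.07, 14.46 and 13.72 M at day 4, and 18.13, 15.41 and 15.33 M at day 7. An FPKM of 1 in a transcript of 1 kb stood on 13.7 to 18.1 reads. Log2 values of the tested genes correlated at r = 0.990 between the day 0 libraries and at 0.985 to 0.992 between the day 7 libraries (across genes, which are not independent replicates). Day 4 replicate 1 stood apart: it correlated at 0.966 and 0.969 with the other day 4 libraries, which correlated at 0.987 with each other. Its gene transcripts held 55.3% of the mapped reads, against 60.9 to 67.1% elsewhere, and transcripts shorter than 0.2 kb held 0.602% of its FPKM, against 0.210 to 0.320%. Unless stated otherwise, levels are mean FPKM ± SD (n = 2 at day 0, n = 3 at days 4 and 7), differences are on the scale of log2(FPKM + 1), which understates the change of low genes, ± SE, and adjusted p values are two-sided and from limma.

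The transcript at the Mir125b-1 locus, the check of the labels, was present before withdrawal and almost absent after it. Mir125b-1 (NR_029822) lies on mm9 chromosome 9, 41390009 to 41390085, in the intron after exon 2 of the noncoding gene 2610203C20Rik. The day 0 libraries held 127 and 76 reads there, the day 4 libraries 0, 0 and 0, and the day 7 libraries 0, 1 and 0. With a floor of 3 reads for the day 4 group, the level was at least 99.7-fold lower at day 4 (the exact 95% interval of the ratio starts at 80.4). At day 7, with 1 read in the group, the ratio of day 0 to day 7 was 330.5 (exact 95% interval 58.6 to 13116.2). These bounds cover counting error only, since sequenced reads are not independent molecules. They do not cover a low level listed as 0 beside the overlapping host gene. The listed reads of the host gene did not follow. They were 1.35 and 1.24 per M mapped reads at day 0. At day 4 they were 9.21, 2.97 and 3.43, and at day 7 they were 2.04, 1.62 and 1.76. The value measures a 77-base precursor locus in an mRNA library and not the mature microRNA.

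**Figure D1:**
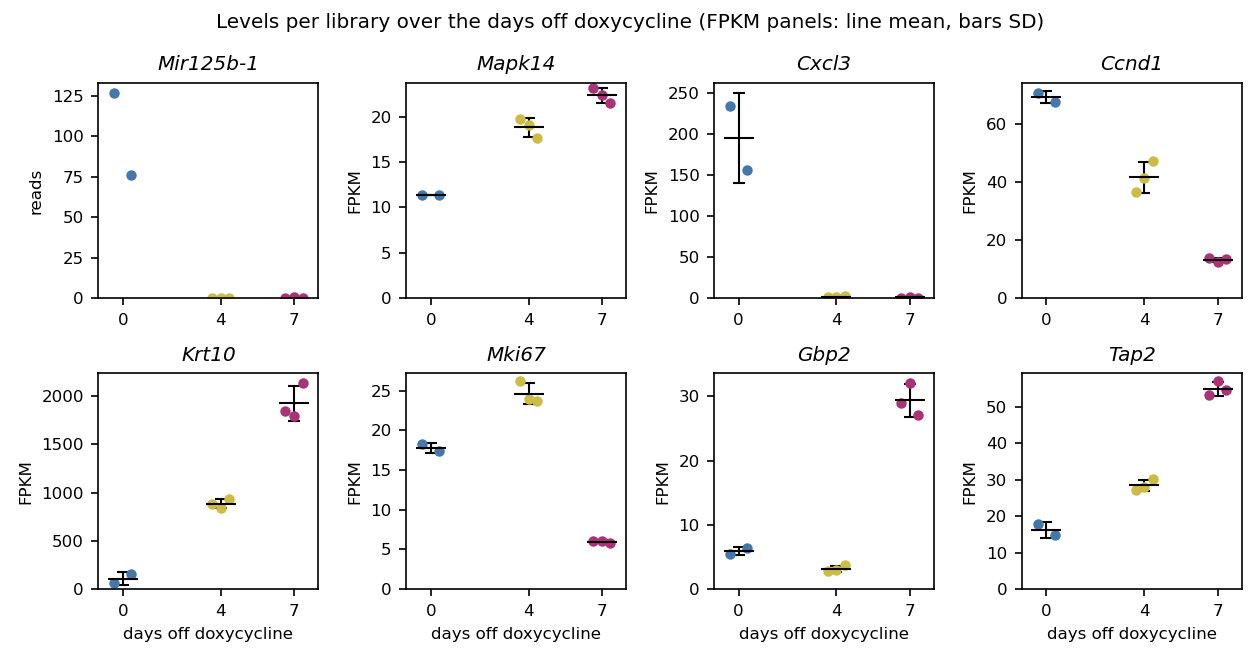
Levels in each library against days off doxycycline, in recovered reads for Mir125b-1 and in FPKM for 7 other genes; each point is 1 library, horizontal lines are group means and bars are SD, neither of which is drawn for Mir125b-1, with its listed zeros. Cxcl3 was near its floor by day 4, Mapk14 was already raised at day 4, Mki67 fell only by day 7, and Gbp2 was lowest at day 4 and highest at day 7.

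The comparison of day 4 with day 0 asked what changed first when doxycycline was withdrawn. The largest falls included genes of the cytokines and chemokines Cxcl3, Csf2, Il24, Il1a and Cxcl1. Cxcl3, a chemokine (NM_203320; chromosome 5, 91215129 to 91217116), fell from 196 ± 54.9 to 1.89 ± 0.498 FPKM (-6.08 ± 0.20, adjusted p = 9.69e-07), Csf2 from 67.9 ± 23.6 to 0.252 ± 0.227 (-5.76), and the noncoding U90926 from 183 ± 55.2 to 3.68 ± 1.32 (-5.30). Il24 fell from 79.0 ± 3.26 to 1.44 ± 0.201 (-5.03, adjusted p = 5.73e-08) and Il1a from 173 ± 15.9 to 5.56 ± 0.945 (-4.74). Cxcl1 fell from 336 ± 68.4 to 17.8 ± 5.50 (-4.19) and Rrad from 31.5 ± 8.23 to 1.48 ± 0.753 (-3.73). The largest rises included Mt4, a metallothionein of stratified epithelium, from 2.59 ± 1.93 to 59.8 ± 5.65 (4.19 ± 0.28, adjusted p = 2.68e-05). Krt10, a keratin of suprabasal cells, rose from 107 ± 69.7 to 883 ± 47.0 (3.20 ± 0.34, adjusted p = 0.000272), Igfl3 from 0.879 ± 0.109 to 18.8 ± 8.23 (3.31) and Sytl1 from 3.61 ± 0.317 to 26.8 ± 5.06 (2.58). In each of these genes no library of one group overlapped the other.

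Of 12117 genes tested, 4259 changed, 2389 of them higher and 1870 lower at day 4. Without day 4 replicate 1, 5531 changed (3326 higher, 2205 lower). Without day 0 replicate 1 the count was 2135, and without day 0 replicate 2 it was 2298. Of the 36 lists tested, 7 were lower and none higher (camera); without day 4 replicate 1, 7 were lower and 3 higher. None of the 7 passed with an estimated correlation.

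In the NF-kB and cytokine list, 13 of 16 members fell and 3 did not pass, with the same counts adjusted over the list alone. Its mean difference was -2.22 (camera adjusted p = 1.83e-11; adjusted p = 0.173 with an estimated correlation). Beside Csf2, Il24 and Il1a, its Ccl20 fell from 65.6 ± 4.30 to 8.37 ± 1.98 (-2.85 ± 0.15). S100a8 (581 ± 0.264 to 127 ± 41.5) and S100a9 (891 ± 41.1 to 164 ± 40.3), on the leukocyte list but also expressed by keratinocytes, fell, while 6 of the 17 genes on that list rose.

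The ERK output and EGFR lists were called lower as well. Of 15 ERK pathway output genes, 9 fell (10 fell and 1 rose adjusted over the list alone), with a mean of -0.83 (camera adjusted p = 6.91e-05; adjusted p = 0.448 with an estimated correlation). Fosl1 fell from 207 ± 20.8 to 37.7 ± 5.24 (-2.43) and Phlda1 from 228 ± 13.1 to 53.7 ± 7.30 (-2.07). Spry2, a feedback inhibitor, fell from 28.5 ± 0.0925 to 6.93 ± 0.910 (-1.90) and Dusp4 from 24.9 ± 5.44 to 8.79 ± 1.42 (-1.40). Dusp6 did not pass (67.1 ± 2.36 and 52.2 ± 15.8, adjusted p = 0.186). Ccnd1, cyclin D1, fell from 69.1 ± 2.13 to 41.7 ± 5.32 (-0.72 ± 0.12, adjusted p = 0.00200). Of 10 EGFR ligands and receptors, 6 fell and 2 rose, with the same counts adjusted over the list alone and a mean of -0.66 (camera adjusted p = 0.0199; adjusted p = 0.448 with an estimated correlation). Areg fell from 45.4 ± 6.88 to 12.2 ± 2.14 (-1.83), Hbegf from 202 ± 7.35 to 82.6 ± 9.97 (-1.29) and Tgfa from 28.6 ± 0.291 to 15.9 ± 1.39 (-0.81), whereas the receptor Erbb3 rose from 6.27 ± 0.393 to 18.4 ± 4.52 (1.39). Under quantile normalization the EGFR call ended (camera adjusted p = 0.0679).

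The matrix remodelling and TGF-beta target lists were also called lower. In the matrix remodelling list 9 of 13 fell and 1 rose, with the same counts adjusted over the list alone and a mean of -1.20 (camera adjusted p = 0.000187; adjusted p = 0.448 with an estimated correlation). Mmp10 fell from 183.1 ± 23.03 to 18.6 ± 5.21 (-3.27), Serpinb2 from 457 ± 75.8 to 69.5 ± 9.78 (-2.70), Plaur from 26.7 ± 3.67 to 6.21 ± 1.22 (-1.95) and Plau from 149 ± 10.5 to 43.2 ± 5.74 (-1.77). Of 14 TGF-beta targets 6 fell and none rose (7 fell adjusted over the list alone), with a mean of -0.58 (camera adjusted p = 0.00458; adjusted p = 0.448 with an estimated correlation). That call ended under quantile normalization (camera adjusted p = 0.0900). Inhba, a subunit of activin, fell from 131 ± 11.6 to 13.3 ± 1.29 (-3.20), Itga5 from 66.0 ± 1.61 to 27.3 ± 5.46 (-1.26), Id1 by 0.73 and Smad7 by 0.60.

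In ribosome biogenesis 9 of 18 genes fell and none rose (12 fell adjusted over the list alone), with a mean of -0.51 (camera adjusted p = 7.73e-05; adjusted p = 0.448 with an estimated correlation). Odc1, which makes polyamines, fell from 101 ± 0.322 to 7.82 ± 0.590 (-3.53), Rrp9 by 0.61, Cad by 0.55 and Mybbp1a by 0.47. Of 21 interferon response genes 11 fell and none rose, with the same counts adjusted over the list alone and a mean of -0.55 (camera adjusted p = 0.00208; adjusted p = 0.767 with an estimated correlation). Usp18 fell from 25.1 ± 2.31 to 6.16 ± 2.74 (-1.95), Ifit1 from 8.77 ± 1.93 to 2.24 ± 1.25 (-1.66), Gbp2 from 5.94 ± 0.650 to 3.15 ± 0.491 (-0.75) and Ifih1 from 4.24 ± 0.0833 to 2.25 ± 0.395 (-0.70). With fry in place of camera the interferon list did not pass (adjusted p = 0.112).

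Epidermal identity moved gene by gene. Of 31 differentiation genes 17 rose and 7 fell (17 and 9 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.130). Klk7, a protease of shedding, rose from 7.95 ± 3.41 to 47.4 ± 5.23 (2.48), the desmosomal Dsg1a from 3.48 ± 0.771 to 19.998 ± 1.30 (2.24) and Klk5 from 3.88 ± 1.14 to 13.3 ± 2.17 (1.56). The transglutaminase Tgm1 fell from 73.4 ± 9.05 to 19.2 ± 2.66 (-1.88). Of 18 basal layer genes 8 fell and 2 rose (9 and 3 adjusted over the list alone; camera adjusted p = 0.0576). Lama3 fell from 272 ± 55.2 to 69.6 ± 14.8 (-1.96) and Itga2 from 52.1 ± 9.01 to 13.8 ± 3.49 (-1.86). Lamb3 fell from 339 ± 64.8 to 127 ± 23.4 (-1.41) and Itga3 from 62.1 ± 10.5 to 28.3 ± 2.46 (-1.10). Trp63, a regulator of the basal layer, fell from 234 ± 1.97 to 141 ± 8.49 (-0.73, adjusted p = 0.00141) and the sort marker Itgb1 from 132 ± 14.3 to 87.9 ± 13.7 (-0.59, adjusted p = 0.0134; 0.122 without day 0 replicate 1). The other sort marker Itga6 (42.1 ± 5.07 and 40.5 ± 2.67), Krt5 (3456 ± 113 and 3697 ± 657) and Krt14 (4259 ± 348 and 4644 ± 797) did not pass. In the hair follicle stem cell list 5 of 15 rose and 1 fell (camera adjusted p = 0.157), with Vdr from 18.8 ± 1.26 to 43.3 ± 10.02 (1.14) and Lgr5 from 0.768 ± 0.195 to 2.52 ± 0.164 (1.00).

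Few cell cycle genes had changed by day 4. Of 26 mitosis genes 3 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.354), and of 25 DNA replication genes 1 fell and none rose (camera adjusted p = 0.134). Mki67, a marker of cycling cells, rose from 17.8 ± 0.626 to 24.6 ± 1.34 (0.44 ± 0.09, adjusted p = 0.00525) and Cenpf from 3.25 ± 0.0324 to 4.69 ± 0.288 (0.42). Ttk fell from 18.9 ± 0.653 to 8.29 ± 0.613 (-1.10) and Ccne1, cyclin E1, from 10.9 ± 0.408 to 4.64 ± 0.758 (-1.09). Cdkn1a, the inhibitor p21, fell from 376 ± 27.7 to 137 ± 9.68 (-1.45 ± 0.12, adjusted p = 7.04e-05). Among 20 p53 targets 5 rose and 7 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.321), in which Mdm2 fell by 1.37, Pmaip1 by 1.23 and Sesn2 by 1.12.

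Among stress kinases and reported targets of miR-125b, single genes rose. Mapk14, the kinase p38α (chromosome 17, 28828287 to 28885350), rose from 11.4 ± 0.0263 to 18.8 ± 1.06 (0.68 ± 0.09, adjusted p = 0.000717), Map2k7, which activates JNK, from 7.36 ± 0.696 to 13.2 ± 2.52 (0.75 ± 0.14, adjusted p = 0.00402). Bmf, a pro-apoptotic gene, rose from 0.130 ± 0.00457 to 0.689 ± 0.0924 (0.58 ± 0.12, adjusted p = 0.00604). Vps4b (16.7 ± 3.87 and 19.0 ± 1.33), Map3k10 (3.68 ± 0.00151 and 3.66 ± 0.326), Map3k11 (13.7 ± 1.04 and 16.4 ± 1.13) and Bak1 (17.3 ± 0.917 and 16.7 ± 3.28) did not pass. Of 24 targets from the literature 12 rose and 4 fell (12 and 5 adjusted over the list alone; mean 0.21, camera adjusted p = 0.130). Mknk2 rose from 25.8 ± 3.04 to 52.5 ± 2.90 (1.00). Tnfaip3, an inhibitor of NF-kB, fell from 175 ± 14.3 to 58.5 ± 5.87 (-1.57) and Prdm1 from 15.6 ± 0.00891 to 6.57 ± 1.31 (-1.15). Part of that list goes back to reports by the same group, so it is not independent evidence. In the p38 and JNK cascade 8 of 24 rose and 7 fell (camera adjusted p = 0.759), with Gadd45a at 37.6 ± 2.13 against 166 ± 25.4 (-2.10) and Mapkapk3 at 18.4 ± 1.95 against 9.46 ± 0.412 (0.89). Of 16 pro-apoptotic genes 5 rose and 4 fell, with a mean of 0.01, a median of -0.03 and a test direction of lower (camera adjusted p = 0.901). Of 13 anti-apoptotic genes 3 rose and 1 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.814), in which Birc3 fell by 1.52 and Bcl2l2 rose by 0.70.

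Metabolic and stress lists were not called at day 4: hypoxia and glycolysis (1 of 18 rose, 6 fell, camera adjusted p = 0.0895), the integrated stress response (2 of 15 rose, 7 fell, 0.0755), oxidative phosphorylation (1 of 19 fell, 0.0576) and heat shock and dissociation stress (5 of 10 fell, 0.130). Hk2, hexokinase, fell from 70.9 ± 2.51 to 35.5 ± 2.06 (-0.98) and Hsp90aa1 from 26.2 ± 2.49 to 15.3 ± 0.323 (-0.74).

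Marker genes of other cell types moved too. Hba-a1, a globin of red cells, rose from 0.447 ± 0.0567 to 22.3 ± 9.95 (3.90), Hbb-b2 from 0.0629 ± 0.0890 to 5.76 ± 1.41 (2.65, and 2.56 without day 0 replicate 1) and Alas2 by 1.81. Of 5 erythroid genes 4 rose (4 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0644). Reads of near-identical globin copies can be shared, and Hba-a2 was listed at 0 in all 3 day 4 libraries. Of 17 leukocyte genes 6 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.157, 0.00944 without day 4 replicate 1), with Lyz2 from 43.2 ± 2.99 to 84.6 ± 24.2 (0.91). Of 11 fibroblast genes 2 rose (none adjusted over the list alone; camera adjusted p = 0.0798, 0.0281 without day 4 replicate 1), with Col1a1 from 72.3 ± 15.9 to 162 ± 55.8 (1.10). Of 11 MHC class I presentation genes 4 rose, with the same count adjusted over the list alone (camera adjusted p = 0.0576, 0.00791 without day 4 replicate 1), among them Tap2 from 16.3 ± 2.16 to 28.4 ± 1.64 (0.77). Fam158a (9.79, 12.27 and 10.64 FPKM at day 4) and Glt8d1 (5.88, 4.77 and 5.10) were listed at 0 in both day 0 libraries, and each overlaps a more abundant gene. The split of 2389 higher and 1870 lower depended on scaling: it was 3099 and 1624 at the same total FPKM, 2134 and 2106 with quantile normalization, and 2321 and 2376 with median-of-ratios scaling. Voom on recovered reads, which also changes the model, gave 3005 and 1763.

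**Figure D2:**
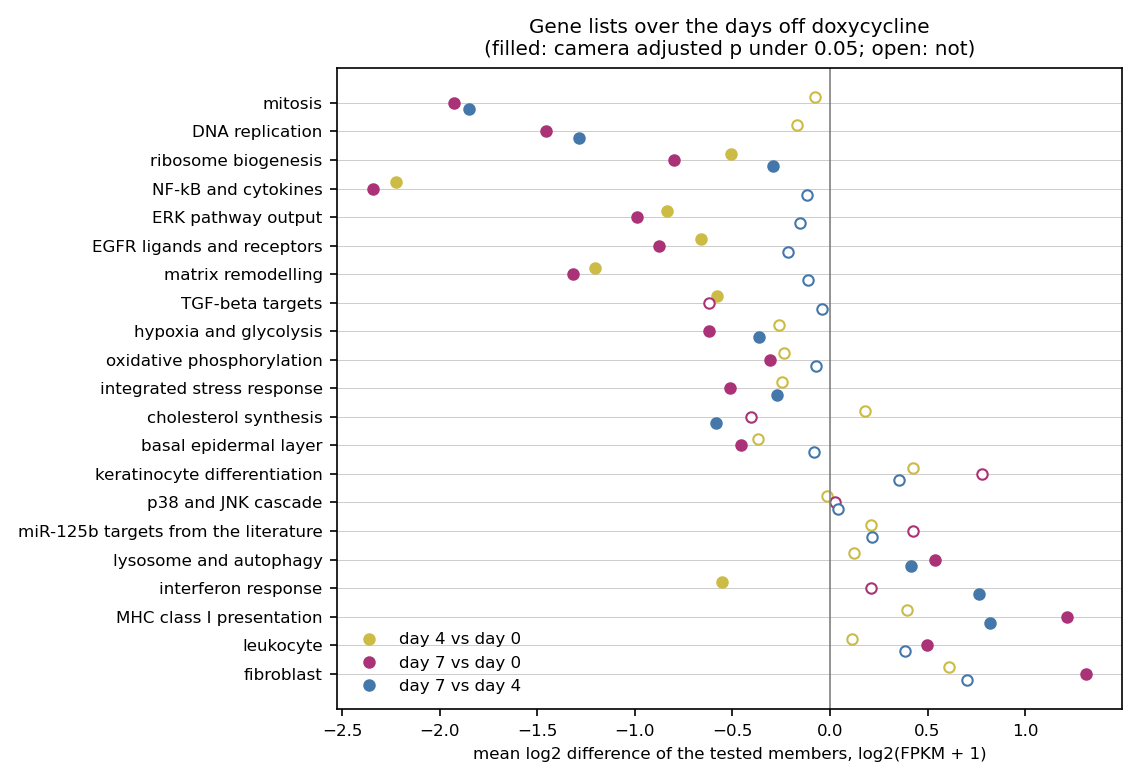
Mean log2 difference of the tested members of 21 gene lists, on the scale of log2(FPKM + 1), for the 3 comparisons; filled points passed camera at an adjusted p of 0.05 with the preset correlation and open points did not, and none passed with an estimated correlation. Mitosis and DNA replication lie far to the left only in comparisons with day 7, and the interferon list changes side between day 4 and day 7.

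The comparison of day 7 with day 0 asked what the cells had become as tumours regressed. Proliferation genes were lower throughout. All 26 mitosis genes fell, with the same count adjusted over the list alone and a mean of -1.93 (camera adjusted p = 2.29e-19; adjusted p = 0.277 with an estimated correlation). Ube2c fell from 51.7 ± 3.93 to 6.87 ± 0.681 (-2.74 ± 0.12), Ttk from 18.9 ± 0.653 to 2.61 ± 0.253 (-2.46), Cdk1 from 24.1 ± 0.338 to 3.91 ± 0.223 (-2.36). Cenpa fell from 33.1 ± 0.505 to 6.46 ± 0.269 (-2.19) and Mki67 from 17.8 ± 0.626 to 5.99 ± 0.163 (-1.43, adjusted p = 4.97e-06). Of 25 DNA replication genes 24 fell and none rose (25 fell adjusted over the list alone), with a mean of -1.46 (camera adjusted p = 4.13e-13; adjusted p = 0.463 with an estimated correlation). Ccne1 fell from 10.9 ± 0.408 to 1.31 ± 0.116 (-2.37) and Tk1 from 19.4 ± 0.355 to 3.20 ± 0.266 (-2.28). Rrm2 fell from 28.3 ± 2.38 to 6.28 ± 0.259 (-2.01) and Uhrf1 from 13.2 ± 0.0556 to 2.77 ± 0.405 (-1.92). Ccnd1 fell from 69.1 ± 2.13 to 13.3 ± 0.697 (-2.29 ± 0.12, adjusted p = 2.47e-06). Of 9 CDK inhibitors 4 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.578): Rbl2 rose by 1.59 and Cdkn2b by 1.30, while Cdkn1a fell from 376 ± 27.7 to 118 ± 4.11 (-1.66).

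Of the tested genes 6949 changed, 4225 higher and 2724 lower; without day 4 replicate 1, whose spread enters the joint fit, 8257 changed (4927 higher, 3330 lower). The median tested gene was 0.13 higher at day 7, and median-of-ratios scaling gave 3489 higher and 3594 lower, and quantile normalization 3495 and 3387. Of 36 lists 15 passed camera, 4 higher and 11 lower, and without day 4 replicate 1 it was 14 (4 higher, 10 lower). None passed with an estimated correlation.

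Krt10 and Igfl3 were again among the largest rises. Igfl3 rose from 0.879 ± 0.109 to 60.05 ± 21.5 (4.97 ± 0.36, adjusted p = 9.51e-06), Krt10 from 107 ± 69.7 to 1925 ± 181 (4.32 ± 0.34), Clca2 from 5.51 ± 1.60 to 119 ± 15.6 (4.21) and Bbox1 from 0.506 ± 0.389 to 22.1 ± 4.88 (3.94). Cst6, a protease inhibitor of the upper layers, rose from 6.40 ± 2.42 to 107 ± 30.4 (3.87), Sprr4 from 0.897 ± 0.360 to 26.7 ± 8.35 (3.83) and Clu, clusterin, from 16.5 ± 1.52 to 223 ± 29.2 (3.67). Fam158a, listed at 0 in both day 0 libraries and overlapping a more abundant gene, was at 10.3, 15.69 and 11.51. Of 31 differentiation genes 19 rose and 9 fell (20 and 10 adjusted over the list alone), with a mean of 0.78, and the list did not pass (camera adjusted p = 0.114). Klk7 rose to 102 ± 5.03 (3.58), Dsg1a to 45.8 ± 2.88 (3.40) and Cdsn from 1.80 ± 0.774 to 14.2 ± 1.26 (2.47), while Tgm1 fell further to 10.97 ± 2.602 (-2.65). In the hair follicle stem cell list 9 of 15 rose and 1 fell (camera adjusted p = 0.0563), with Lgr5 at 6.34 ± 1.12 (2.05) and Vdr at 70.1 ± 10.6 (1.84).

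Basal layer genes were lower by a small margin: 9 of 18 fell and 4 rose, with the same counts adjusted over the list alone and a mean of -0.45 (camera adjusted p = 0.0410; adjusted p = 0.633 with an estimated correlation). That call ended under 7 alternatives, among them quantile normalization (0.291) and leaving out day 0 replicate 1 (0.0546) or day 4 replicate 1 (0.0696). Itga2 fell from 52.1 ± 9.01 to 8.82 ± 1.52 (-2.44), Lama3 to 53.3 ± 8.63 (-2.33), Lamb3 to 109 ± 11.6 (-1.62) and Itga3 to 23.5 ± 0.124 (-1.36). Trp63 fell to 137 ± 2.57 (-0.77, adjusted p = 0.000387) and Itgb1 to 92.6 ± 3.18 (-0.50, adjusted p = 0.0154; 0.130 without day 0 replicate 1). Krt5 (3283 ± 93.1), Krt14 (4506 ± 170) and Itga6 (41.4 ± 2.32) did not pass.

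Inflammatory, growth factor and matrix genes stayed low. U90926 fell to 0.212 ± 0.0698 (-7.21), Cxcl3 to 0.956 ± 0.216 (-6.63, adjusted p = 1.72e-07), Csf2 to 0.165 ± 0.0324 (-5.84) and Il1a to 3.64 ± 0.658 (-5.24). Il24 fell to 1.60 ± 0.148 (-4.94), Inhba to 3.49 ± 0.696 (-4.88) and the defensin Defb14 from 92.3 ± 8.25 to 2.33 ± 0.915 (-4.85). In the NF-kB and cytokine list 13 of 16 fell and none rose (13 and 1 adjusted over the list alone), with a mean of -2.34 (camera adjusted p = 2.36e-08; adjusted p = 0.277 with an estimated correlation). Of 15 ERK output genes 11 fell and 2 rose, with the same counts adjusted over the list alone and a mean of -0.99 (camera adjusted p = 0.000661; adjusted p = 0.476 with an estimated correlation). Fosl1 was at 24.8 ± 4.39 (-3.02), Phlda1 at 29.7 ± 5.86 (-2.92) and Etv4 at 2.61 ± 0.161 (-1.73). Dusp6 was at 67.0 ± 10.4 against 67.1 ± 2.36. Of 10 EGFR ligands and receptors 5 fell and 2 rose (6 and 2 adjusted over the list alone), with a mean of -0.88 (camera adjusted p = 0.0203, 0.0582 under quantile normalization; adjusted p = 0.313 with an estimated correlation). Areg fell to 7.69 ± 0.481 (-2.41) and Ereg from 15.0 ± 0.225 to 2.11 ± 0.299 (-2.37), and Erbb3 rose to 22.4 ± 0.0768 (1.69). In the matrix list 8 of 13 fell and 2 rose, with the same counts adjusted over the list alone and a mean of -1.32 (camera adjusted p = 0.00355; adjusted p = 0.476 with an estimated correlation). Mmp13 fell from 1688 ± 253 to 97.7 ± 30.2 (-4.14) and Serpinb2 at 30.0 ± 6.26 (-3.89). TGF-beta targets did not pass (6 of 14 fell, 1 rose, camera adjusted p = 0.0563).

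Biosynthesis and metabolism genes were lower. In ribosome biogenesis 16 of 18 fell and none rose (17 fell adjusted over the list alone), with a mean of -0.80 (camera adjusted p = 2.22e-07; adjusted p = 0.313 with an estimated correlation). Odc1 was at 6.86 ± 1.52 (-3.72), Cad at 6.68 ± 0.361 (-1.004) and Nop56 at 17.4 ± 0.595 (-0.90). In hypoxia and glycolysis 11 of 18 fell and 1 rose, with the same counts adjusted over the list alone and a mean of -0.62 (camera adjusted p = 0.00141; adjusted p = 0.515 with an estimated correlation). Ndrg1 fell from 728 ± 16.4 to 229.9 ± 31.7 (-1.67), Ldha from 672 ± 16.1 to 251 ± 19.3 (-1.42) and Hk2 to 30.0 ± 1.77 (-1.22). In the integrated stress response 9 of 15 fell and none rose, with the same counts adjusted over the list alone and a mean of -0.51 (camera adjusted p = 0.00133; adjusted p = 0.313 with an estimated correlation). Sesn2 fell by 1.18, Phgdh by 1.06 and Shmt2 by 0.96. In oxidative phosphorylation 5 of 19 fell (3 adjusted over the list alone), with a mean of -0.31 (camera adjusted p = 0.0203; adjusted p = 0.688 with an estimated correlation), and Ndufa4 fell from 254 ± 26.6 to 119 ± 2.93 (-1.08). That call ended without day 0 replicate 2 (0.0614), under quantile normalization (0.0979) and with fry (0.207). Lysosome and autophagy genes were higher: 13 of 19 rose and 1 fell, with the same counts adjusted over the list alone and a mean of 0.54 (camera adjusted p = 0.0339, 0.0614 without day 0 replicate 2; adjusted p = 0.633 with an estimated correlation). Ulk1 rose from 10.5 ± 0.346 to 21.0 ± 1.08 (0.93) and Lamp2 from 123 ± 2.41 to 227 ± 1.33 (0.88). NRF2 targets (4 of 12 rose, 6 fell, camera adjusted p = 0.216) and cholesterol synthesis (3 of 16 rose, 7 fell, 0.0563; mean -0.41, and -0.16 without Fdft1) did not pass.

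Antigen presentation genes rose together with markers of leukocytes and fibroblasts. Of 11 MHC class I presentation genes 10 rose and none fell, with the same counts adjusted over the list alone and a mean of 1.22 (camera adjusted p = 0.000661; adjusted p = 0.476 with an estimated correlation). H2-T23 rose from 8.31 ± 0.283 to 33.8 ± 0.428 (1.90), the peptide transporter genes Tap2 from 16.3 ± 2.16 to 55.0 ± 1.90 (1.70) and Tap1 from 24.8 ± 0.431 to 66.0 ± 3.72 (1.38). Psmb9 rose from 20.2 ± 0.273 to 65.6 ± 2.41 (1.65). Of 17 leukocyte genes 12 rose and 2 fell, with the same counts adjusted over the list alone and a mean of 0.50 (camera adjusted p = 0.0350; adjusted p = 0.663 with an estimated correlation). That call ended without day 0 replicate 1 (0.0605) or day 7 replicate 3 (0.0652). The MHC class II genes Cd74 (141 ± 27.7 to 686 ± 41.9, 2.28), H2-Aa (58.8 ± 14.3 to 268 ± 11.95, 2.19) and H2-Ab1 (81.7 ± 7.59 to 341 ± 17.6, 2.05) rose, and S100a9 fell to 72.1 ± 37.4 (-3.73). Of 11 fibroblast genes 9 rose and none fell, with the same counts adjusted over the list alone and a mean of 1.31 (camera adjusted p = 0.0185; adjusted p = 0.633 with an estimated correlation). Col1a1 rose from 72.3 ± 15.9 to 368 ± 118 (2.30) and Col1a2 from 52.0 ± 11.2 to 264 ± 83.9 (2.29). Lists that share mesenchymal genes moved beside them: 6 of 9 EMT genes rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.101), with Vim from 38.3 ± 5.48 to 105 ± 6.85 (1.44). Of 7 endothelial genes 5 rose (camera adjusted p = 0.0647), with Cdh5 from 0.655 ± 0.0631 to 2.41 ± 0.511. Of 5 muscle genes 3 rose (0.184), of 5 erythroid genes 3 rose (0.216), of 4 melanocyte genes 2 rose, and the only tested adipocyte gene, Fabp4, rose from 2.86 ± 0.589 to 13.9 ± 0.772 (1.96). In the interferon list 5 of 21 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.753): Gbp2 rose to 29.4 ± 2.55 (2.13), while Isg15 fell from 75.8 ± 7.09 to 28.5 ± 7.57 (-1.41).

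Some of the reported targets and stress kinases were higher at day 7 than at day 0. Bmf rose from 0.130 ± 0.00457 to 2.54 ± 0.204 (1.65 ± 0.12, adjusted p = 9.54e-06). Map2k7 rose from 7.36 ± 0.696 to 16.4 ± 0.614 (1.06 ± 0.14, adjusted p = 0.000263) and Mapk14 from 11.4 ± 0.0263 to 22.4 ± 0.806 (0.91 ± 0.09, adjusted p = 4.69e-05). Vps4b, an ATPase of endosomal sorting, rose from 16.7 ± 3.87 to 28.1 ± 0.661 (0.73 ± 0.13, adjusted p = 0.00145). Map3k11 rose from 13.7 ± 1.04 to 18.4 ± 1.42 (0.40 ± 0.11, adjusted p = 0.0107), a call that ended under median-of-ratios scaling (0.0903) and without day 0 replicate 1 (0.0934). Map3k10 (4.57 ± 0.267) and Bak1 (20.05 ± 0.533) did not pass. Of 24 targets from the literature 13 rose and 5 fell (14 and 5 adjusted over the list alone; mean 0.43, camera adjusted p = 0.0647). In the p38 and JNK cascade 9 of 24 rose and 9 fell, with a median of 0.18 and a mean of 0.02 but a test direction of lower, because camera compared them with other genes (camera adjusted p = 0.785). Of 10 AP-1 genes 5 rose and 3 fell (0.891), with Fos from 679 ± 99.8 to 1544 ± 49.3 (1.19) and Atf3 from 200.3 ± 18.5 to 482 ± 91.6 (1.25). In ESCRT and endosomal sorting 10 of 22 rose and 4 fell (0.891), in which Stam fell by 1.18. Pro-apoptotic (7 of 16 rose, 5 fell, 0.891) and anti-apoptotic genes (6 of 13 rose, 2 fell, 0.578) and p53 targets (8 of 20 rose, 9 fell, 0.413) did not pass. Neither did the Notch list (2 of 10 rose, 1 fell, median 0.06, mean 0.10, test direction lower, 0.943), in which Notch1 rose by 0.96, nor Wnt targets (3 of 7 rose, 2 fell, 0.808), in which Axin2 rose by 0.62 and Wif1 fell by 1.68. Heat shock and dissociation stress did not pass (1 of 10 rose, 4 fell, 0.0701). That list holds heat shock and chaperone genes alone, so it does not settle whether handling differed.

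The comparison of day 7 with day 4 asked which changes came late. Here proliferation genes fell and interferon genes rose. All 26 mitosis genes fell, with the same count adjusted over the list alone and a mean of -1.85 (camera adjusted p = 3.97e-40; adjusted p = 0.124 with an estimated correlation). Of the DNA replication genes 24 of 25 fell, with the same count adjusted over the list alone and a mean of -1.29 (camera adjusted p = 4.50e-26; adjusted p = 0.371 with an estimated correlation). Ube2c fell from 44.8 ± 4.73 to 6.87 ± 0.681 (-2.54 ± 0.11, adjusted p = 4.18e-06), Birc5, survivin, from 36.8 ± 7.48 to 6.30 ± 0.221 (-2.35) and Cdk1 from 20.3 ± 2.40 to 3.91 ± 0.223 (-2.11). Tk1 fell from 16.1 ± 1.11 to 3.20 ± 0.266 (-2.03), Mki67 from 24.6 ± 1.34 to 5.99 ± 0.163 (-1.87 ± 0.08, adjusted p = 4.18e-06) and Ccnd1 from 41.7 ± 5.32 to 13.3 ± 0.697 (-1.57). Cdkn1a (137 ± 9.68 and 118 ± 4.11) did not pass. Other falls were in Prl8a9, from 21.3 ± 11.9 to 2.73 ± 1.17 (-2.45), Lce3c, from 11.6 ± 3.28 to 1.29 ± 0.0635 (-2.43), and Sprr2f, from 57.0 ± 4.99 to 10.6 ± 3.35 (-2.36), all members of families whose reads can be shared.

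Cxcl9, a chemokine induced by interferon gamma, rose from 1.28 ± 0.340 to 17.3 ± 0.730 (3.02 ± 0.12, adjusted p = 3.71e-06) and Gbp2 from 3.15 ± 0.491 to 29.4 ± 2.55 (2.88 ± 0.11, adjusted p = 3.71e-06). Of 21 interferon response genes 12 rose and none fell, with the same counts adjusted over the list alone and a mean of 0.76 (camera adjusted p = 0.000103; adjusted p = 0.661 with an estimated correlation). Gbp3 rose from 1.85 ± 0.511 to 4.84 ± 0.114 (1.05) and Ifih1 from 2.25 ± 0.395 to 5.16 ± 0.679 (0.92). Of 11 MHC class I genes 10 rose and none fell, with the same counts adjusted over the list alone and a mean of 0.82 (camera adjusted p = 1.33e-05; adjusted p = 0.474 with an estimated correlation). H2-T23 rose from 12.4 ± 2.05 to 33.8 ± 0.428 (1.39) and Tap2 from 28.4 ± 1.64 to 55.0 ± 1.90 (0.93). Markers of other cells moved beside them: 10 of 17 leukocyte genes rose and 2 fell (11 and 2 adjusted over the list alone; camera adjusted p = 0.0575), with Cd74 from 240.0 ± 70.6 to 686 ± 41.9 (1.56) and Ptprc from 3.88 ± 0.869 to 7.14 ± 0.663 (0.75). Of 11 fibroblast genes 6 rose (8 adjusted over the list alone; camera adjusted p = 0.0528), with Dcn from 19.6 ± 8.42 to 44.9 ± 11.8 (1.22). Of 5 erythroid genes 4 fell and 1 rose (camera adjusted p = 0.0574).

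The other large rises were in Fcgbp, from 2.17 ± 0.265 to 22.3 ± 2.75 (2.88), Mmp11, from 4.403 ± 0.478 to 26.9 ± 9.69 (2.32), Sprr4, from 5.04 ± 2.59 to 26.7 ± 8.35 (2.23), Serpina3j, from 0.330 ± 0.121 to 5.73 ± 3.45 (2.23), and Clca2, from 25.1 ± 5.02 to 119 ± 15.6 (2.20). Pcp4 was listed at 0.31, 0 and 0.36 FPKM at day 4 and at 14.43, 2.70 and 15.0 at day 7. Krt10 rose from 883 ± 47.0 to 1925 ± 181 (1.12 ± 0.31, adjusted p = 0.0274), a call lost without day 4 replicate 2 (0.0584) or 3 (0.0551), without day 7 replicate 1 (0.0708), 2 (0.0653) or 3 (0.0828), with no filter (0.0672) and with voom (0.0724). Among 31 differentiation genes 12 rose and 3 fell (13 and 5 adjusted over the list alone; camera adjusted p = 0.230). Lce1a1 rose from 2.63 ± 0.738 to 12.4 ± 3.04 (1.88), Lor, loricrin, from 13.2 ± 4.39 to 46.9 ± 8.35 (1.78), Cdsn by 1.59 and Dsg1a by 1.16. Krt5, Krt14, Itga6, Itgb1 and Trp63 did not pass, with differences of -0.16 to 0.08.

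Cholesterol synthesis fell in 11 of 16 genes and rose in 1, with the same counts adjusted over the list alone and a mean of -0.58 (camera adjusted p = 2.34e-06; adjusted p = 0.434 with an estimated correlation). Without Fdft1 the mean was -0.33 (camera adjusted p = 4.62e-05; adjusted p = 0.474 with an estimated correlation). Sqle fell from 54.8 ± 5.95 to 34.8 ± 0.821 (-0.63) and Nsdhl from 29.4 ± 4.91 to 17.8 ± 1.69 (-0.68). Fdft1 was at 18.37, 19.38 and 20.86 FPKM at day 4 and listed at 0 in all day 7 libraries, as were Mxd3 (7.61, 8.80 and 8.67 at day 4) and Pisd-ps1 (24.06, 4.99 and 11.06); each overlaps a more abundant gene. Ribosome biogenesis fell in 8 of 18 (9 adjusted over the list alone), with a mean of -0.29 (camera adjusted p = 4.72e-06; adjusted p = 0.434 with an estimated correlation). Nop56 fell from 27.2 ± 3.64 to 17.4 ± 0.595. Hypoxia and glycolysis fell in 4 of 18 and rose in 1, with the same counts adjusted over the list alone and a mean of -0.36 (camera adjusted p = 6.12e-05; adjusted p = 0.477 with an estimated correlation; 0.0558 with fry). Car9 fell from 12.1 ± 4.41 to 4.54 ± 1.42 (-1.23) and Ndrg1 by 0.92, while the glucose transporter Slc2a1 rose from 382 ± 22.8 to 566 ± 52.8 (0.56). The integrated stress response fell in 6 of 15, with the same count adjusted over the list alone and a mean of -0.27 (camera adjusted p = 0.000909; adjusted p = 0.371 with an estimated correlation). Aldh1l2 fell by 0.75 and Shmt2 by 0.60. Lysosome and autophagy rose in 9 of 19 and fell in none (16 rose adjusted over the list alone), with a mean of 0.41 (camera adjusted p = 0.00192; adjusted p = 0.661 with an estimated correlation). Gabarapl1 rose from 49.4 ± 10.4 to 90.6 ± 7.09 (0.88) and Map1lc3b from 33.3 ± 9.09 to 54.5 ± 5.12 (0.73).

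Bmf rose from 0.689 ± 0.0924 to 2.54 ± 0.204 (1.07 ± 0.11, adjusted p = 0.000205) and Vps4b from 19.0 ± 1.33 to 28.1 ± 0.661 (0.55 ± 0.12, adjusted p = 0.0108). Mapk14 (difference 0.24, adjusted p = 0.0570), Map2k7 (0.31), Map3k10 (0.26), Map3k11 (0.16), Bak1 (0.27) and Dusp6 (0.38) did not pass. Of 24 targets from the literature 6 rose and none fell (camera adjusted p = 0.144), among them Sgpl1 from 23.3 ± 0.917 to 35.8 ± 1.06 (0.60) and Vdr by 0.70. NF-kB and cytokine genes had a median of 0.04 and a mean of -0.12, with 2 of 16 higher and 4 lower (camera adjusted p = 0.158): Ccl2 fell from 48.9 ± 4.91 to 16.0 ± 1.60 (-1.56) and Icam1 rose by 0.50. In the matrix list, with 2 of 13 higher and 3 lower, the median was 0.25 and the mean -0.11 (camera adjusted p = 0.665): Mmp13 fell from 368 ± 101 to 97.7 ± 30.2 (-1.91), while Mmp14 rose from 48.0 ± 7.75 to 85.0 ± 2.18 (0.82) and Mmp2 by 1.01. TGF-beta targets had a median of 0.07 and a mean of -0.04 (camera adjusted p = 0.605). The p38 and JNK cascade (median 0.08, mean 0.04, camera adjusted p = 0.730) and p53 targets (0.05, 0.08, 0.833) had a test direction of lower against the other genes. ERK output (2 of 15 rose, 5 fell, camera adjusted p = 0.0840) and oxidative phosphorylation (1 of 19 fell, 0.138; 5.17e-06 without day 4 replicate 1) did not pass.

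Between day 4 and day 7, 3290 genes changed, 2277 higher and 1013 lower; without day 4 replicate 1 it was 4285 (2588 and 1697), and without day 7 replicate 1, 2 or 3 it was 1893, 1895 or 2131. The balance narrowed but kept its direction under other scalings: 1587 higher and 1512 lower with median-of-ratios scaling, 1813 and 1584 with quantile normalization, and 1608 and 1524 at the same total FPKM. With voom on recovered reads, which changes the values and the model as well, it was 1494 and 1713. Of 36 lists 9 passed camera, 3 higher and 6 lower; without day 4 replicate 1 it was 10 (3 and 7). None passed with an estimated correlation.

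Over the whole course 6859 genes changed at any time (limma moderated F; 8431 without day 4 replicate 1). Of the changes against day 0, 3784 were called at both days in the same direction, 2200 higher and 1584 lower, and 43 in opposite directions. Independent lists of these sizes would share 1253 genes in the same direction, and simulated libraries with no change and the same shared day 0 group gave a mean of 0.03. Across genes, which are not independent replicates, the 2 differences correlated at r = 0.851, against 0.599 in the simulation, because both contain the same day 0 libraries. Splitting the 2 of them would have left 1 for each comparison and was not done, so part of the overlap can come from their shared error; without day 0 replicate 1 it was 1970 genes and without day 0 replicate 2 it was 2109. Genes higher at day 4 and higher still at day 7 numbered 992, those lower and lower still 301, and 96 rose by day 4 and then fell, while 160 fell and then rose. Both steps contain the day 4 libraries with opposite sign, so error in these libraries alone can make genes of the last 2 kinds. No simulated value was set beside these counts.

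Transcripts with a miR-125b site rose more than others; the mature microRNA was not measured, and its loss was not separated from other effects of withdrawal. Of 11513 tested genes with a 3′UTR in the annotation, 1767 carried CTCAGGG, the match to the microRNA's seed. At day 4 their median difference was 0.17, against 0.03 for genes without it, and at day 7 it was 0.31 against 0.09. The coefficient of carrying the site, with UTR length and GC content in the model, was 0.11 at day 4 and 0.17 at day 7 against day 0, and 0.06 between day 4 and day 7. In each comparison it lay above all 518 control 7-mers of the same GC count (permutation p = 0.00193, two-sided by absolute value, the smallest these controls allow). Bmf carries 4 such sites, Sgpl1 3, Vdr 2, and Mapk14, Map2k7, Map3k11, Vps4b, Erbb3, Mknk2, Tnfaip3 and Prdm1 1 each; Tnfaip3 and Prdm1 fell by day 4, when 4 of the 24 literature targets were called lower. Map3k10 and Bak1 also carry 1 site each and did not pass. The shift is small beside the changes of single genes, and sites were counted in the longest 3′UTR whether or not it is the expressed one.

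**Figure D3:**
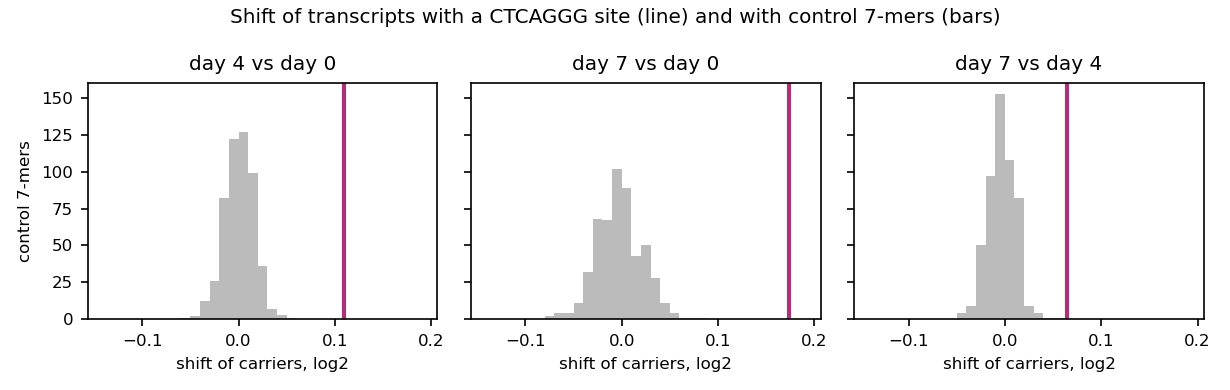
Histograms of the log2 coefficient of carrying each of 518 control 7-mers in the 3′UTR, for the 3 comparisons, with a vertical line at the coefficient of CTCAGGG. The line lies to the right of every control, at 0.11, 0.17 and 0.06.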

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

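The tests of Mir125b-1, of the listed zeros, of the MHC class I rise and of other splits of the libraries were chosen after the result was seen, and the tests of AU-rich transcripts and of site number were written before their results were seen.

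The fall of Mir125b-1 from 127 and 76 reads to 0 or 1 was weighed because it checks the day 0 labels. A day 0 label on a later library, or the reverse, was excluded, since the lowest day 0 library held 76 reads and the highest later one 1; day 4 and day 7 libraries are not told from each other by these reads. The listed host gene reads did not fall: the lowest day 4 value, 2.974 reads per M mapped reads, lay above the highest day 0 value of 1.349. Lower transcription of the host gene was still not excluded. At day 0 the host, at 0.53 and 0.49 FPKM, was the lesser gene of the overlapping pair, so its day 0 value may be listed too low. A day 0 level hidden as a listed 0 by the overlapping host was excluded, since the host reached at most 3.63 FPKM after day 0 and Mir125b-1 at least 153.94 at day 0. A low remaining level listed as 0 was not excluded, since the host was listed above Mir125b-1 in all day 4 libraries. Doxycycline withdrawal ending a transgene at this sequence may explain it, but libraries that would separate this from other effects of the food change were not used here.

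Listed zeros were searched among genes on a single chromosome whose longest transcript had 200 or more bases. Mir125b-1, with 77 bases and listed at 0 at day 4, was left out by this limit. Of these genes, 12 were listed at exactly 0 in every library of a group and at a mean of 5 FPKM or more in another: Ccdc64b, Cd97, Cyb5r2, Fam158a, Fdft1, Glt8d1, Kdelr3, Ly6f, Mxd3, Pcp4, Pisd-ps1 and Tpt1. Overlap with a more abundant gene during abundance estimation was consistent with the data: 83.3% of the 12 overlapped one, against 3.1% of 8458 other genes. In overlapping pairs the lesser gene stood at 0 in 35.7% of 1764 values, against 7.0% of 12427 values of neighbouring pairs. A real switch cannot be told apart for the set, since 6 of 12 had graded levels, and Pcp4 and Ly6f overlap no such gene. The changes of the other 10 should be read as possible products of estimation, Fdft1 included.

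MHC class I genes rose by a mean of 0.82 from day 4 to day 7, beside markers of other cells, a call lost with an estimated correlation (adjusted p = 0.474). Scaling could not be tested this way, since the list was compared with other genes and a scaling factor shifts both nearly alike. The mean rise above that of other genes was 0.74, and 0.71 to 0.73 under 3 other scalings (largest camera adjusted p = 5.16e-07). The median tested gene rose by 0.094 as deposited and by 3.61e-04 with median-of-ratios scaling, both small beside the list's mean of 0.82. Leukocyte RNA cannot be told apart: the median of 17 markers rose by 0.488 and that of 11 MHC genes by 0.846 (difference -0.358, smaller in size than the markers' SD of 0.799), and Cd74 rose to 686 ± 41.9 FPKM; the permutation p of 0.0169 (100000 resamples) alone would have excluded it, the bound by the SD was added after these values were known, and a first run without Cd74, H2-Aa, H2-Ab1, S100a8 and S100a9 was dropped. Fibroblast RNA cannot be told apart either (median 0.623, difference -0.223, permutation p = 0.237; Col1a1 at 368 ± 118), although the sort should remove both cell types. An interferon response of the tumour cells may also explain it, as Cxcl9 and Gbp2 rose, but no test here separates it from added cells.

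The other results were picked out because the list's change against day 0 differed between day 4 and day 7, by the test of day 7 against day 4. All were called by camera at the preset correlation and none with an estimated one, whose adjusted p follows each difference. Mitosis (difference -1.85; 0.124) and DNA replication (-1.29; 0.371) were called lower between day 4 and day 7 but not between day 0 and day 4, when 1 called gene of each had fallen (Ttk and Ccne1) and 3 mitosis genes had risen. The interferon response (0.76, 0.661) was below day 0 at day 4 (adjusted p = 0.767 with an estimated correlation) and, not called, above it at day 7. Hypoxia and glycolysis (-0.36, 0.477), ribosome biogenesis (-0.29, 0.434) and the integrated stress response (-0.27, 0.371) were lower at day 7 than at day 4. Lysosome and autophagy (0.41, 0.661) rose between the days, and cholesterol synthesis (-0.58, 0.434) had means against day 0 of 0.18 at day 4 and -0.41 at day 7, neither called. Without Fdft1 these means were 0.18 and -0.16, and the difference was -0.33 (camera adjusted p = 4.62e-05; adjusted p = 0.474 with an estimated correlation). The MHC class I difference of 0.82 (0.474) is weighed above.

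Of the 10 splits of the 6 day 4 and day 7 libraries into 3 and 3, only 1, the real one, called 3290 genes, and the highest other called 2. That is too few splits for a share under 0.05.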

How the results depend on the processing

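Of the alternatives, limma-voom on recovered reads, scaling to the same total FPKM and the cholesterol list without Fdft1 were chosen after the result was seen, as were all alternatives of the overlap and of replicate agreement, and the others before. No list or named-gene result that was called in either setting reversed. A change of sign in a result called in neither was counted as the same. Examples are the pro-apoptotic list at day 4 and the Notch list at day 7 against day 0, lower by camera and higher by fry. Of 1935 alternatives of 108 list results 1771 were the same, 115 stronger and 49 weaker, and of 9455 alternatives of 503 named-gene results 8914 were the same, 132 stronger and 409 weaker. The balance of higher and lower genes did change sides under some alternatives. With median-of-ratios scaling it was 2321 and 2376 at day 4 and 3489 and 3594 at day 7 against day 0. With voom it was 1494 and 1713 between day 4 and day 7. Where a value moved, the cause was not tested unless stated.

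Genes changed at day 4 against day 0 (4259) ranged from 2135 to 5531 when a library was left out, with 2135 without day 0 replicate 1 and 2298 without day 0 replicate 2, each of which leaves a lone day 0 library taken to vary like the other groups. At day 7 against day 0 (6949) the range was 5170 to 8257, and a mean FPKM of 5 or more gave 4512 because only 7762 genes were tested. Between day 7 and day 4 (3290) it was 1893 to 4285, with 1893, 1895 and 2131 without day 7 replicates 1, 2 and 3, 2078 at a mean FPKM of 5 or more and 2189 with transcripts kept apart. Genes changed at any time (6859) ranged from 4990 to 8431, with 4492 at a mean FPKM of 5 or more. The overlap of changes against day 0 (3784) ranged from 1970 to 4909, with 1970 and 2109 without day 0 replicates 1 and 2. Replicate agreement (median r 0.9869 over 7 pairs of libraries, from 0.966 with day 4 replicate 1) ranged from 0.9852 to 0.9874, with 0.9731 on log2(FPKM + 0.1) and 0.9539 with transcripts kept apart.

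Lists called by camera at day 4 against day 0 (7) ranged from 7 to 11 when a library was left out, 11 without day 4 replicate 3, and were 12 with no filter and 14 with fry. At day 7 against day 0 (15) the range was 14 to 17, with 28 by fry. Between day 7 and day 4 (9) it was 9 to 14, with 14 without day 4 replicate 3. With an estimated correlation in camera, 0 lists were called in each of the 3 comparisons. With a library left out, the miR-125b site coefficient ranged from 0.0984 to 0.1175 at day 4 and 0.1686 to 0.1792 at day 7 against day 0, and from 0.0564 to 0.0755 between them. Over all alternatives the ranges were 0.0916 to 0.1312, 0.1589 to 0.2111 and 0.0560 to 0.0798.

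With the replicate number as a replicate block, 4376, 6879 and 3409 genes were called in the 3 comparisons (day 4 and day 7 against day 0, day 7 against day 4) and 6916 at any time, and 11, 17 and 11 lists. It added calls of the basal layer (adjusted p = 0.0315), hypoxia and glycolysis (0.0321), oxidative phosphorylation (0.0273) and fibroblast (0.0315) lists at day 4, of hair follicle stem cell (0.0407) and TGF-beta targets (0.0365) at day 7 against day 0, and of fibroblast (0.0216) and erythroid (0.0441) between them, all with camera, and it ended no list call. Deviations of libraries from their group means correlated above 0 in all 7 same-numbered pairs (mean r 0.161, 0.00776 to 0.377) and at a mean of -0.0818 in the 14 others (-0.29 to 0.175). Deviations sum to 0 within a group, so a positive mean in same-numbered pairs tends to bring that of the others below 0. For the same reason the 7 pairs are not independent. Every library correlated best with one of its own number except day 4 replicate 3 and day 7 replicate 3. This is a hint that the numbers may mark something shared, but only 4 of the 7 pairs exceeded 0.1 and the labels name nothing shared, so this pairing was not used.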

Other observations

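The tests below of AU-rich transcripts and of site number were written before their results were seen, while the scan of all 7-mers and the genes named here were chosen after the result was seen.

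Some genes moved in opposite directions on the way to day 4 and from there to day 7. The histone chaperone Asf1b rose from 3.06 ± 0.0428 to 6.71 ± 1.25 FPKM (0.91, limma adjusted p = 0.00154) and then fell to 2.03 ± 0.209 (-1.34, adjusted p = 0.000153). Cdca3, which acts at entry into mitosis, rose from 18.3 ± 0.721 to 23.8 ± 1.99 (0.36, adjusted p = 0.0256) and fell to 5.04 ± 0.357 (-2.03), as Mki67 did. In the other direction, the chemokine Cxcl9 fell from 4.27 ± 0.555 to 1.28 ± 0.340 and rose to 17.3 ± 0.730, and Cxcl10 fell from 14.02 ± 1.86 to 7.55 ± 1.25 (-0.82) and rose to 34.6 ± 1.15 (2.07, adjusted p = 1.26e-05). Cd274, a ligand of PD-1, a receptor on T cells, fell from 3.85 ± 0.0649 to 2.45 ± 0.201 (-0.49, adjusted p = 0.00559). It then rose to 5.63 ± 0.336 (0.95, adjusted p = 0.000155). In all, 96 genes rose and then fell and 160 fell and then rose (n = 2, 3 and 3). Error in the day 4 libraries, which enter both steps with opposite sign, can make such genes, and its share was not estimated.

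Transcripts carrying TATTTAT, an AU-rich element found in many short-lived cytokine mRNAs, were lower at day 4. The coefficient over 3247 genes was -0.091, below all 46 control 7-mers of A and T (lower bound of their middle 95%, -0.037; permutation p = 0.0213, the smallest possible). It was -0.087 at day 7 against day 0 and 0.004 between day 4 and day 7 (permutation p = 0.936). Faster decay of such transcripts and lower transcription of the same genes are both hypotheses, and neither was measured here.

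Genes with 2 or more miR-125b sites (281) had a coefficient of 0.295 at day 7 against day 0, and genes with 1 site (1486) had 0.153. The difference of 0.142 lay above the upper bound of 0.11 of the middle 95% of 1000 reassignments (permutation p = 0.00799); it was 0.103 at day 4 (permutation p = 0.005) and 0.039 between the days (permutation p = 0.114). In a scan of 15703 7-mers CTCAGGG had the highest z in all 3 comparisons (7.13, 7.88 and 5.44), although TATTTAT was larger in size at day 4 (z = -7.15). The difference was not tested against other 7-mers counted in the same way.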
